A study of Danio rerio with 24 samples.

How the data were processed

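The series covers 24 samples of adult zebrafish brain and whole kidney marrow. The 14 RNA-seq libraries were analysed, and the 10 ATAC-seq libraries were not analysed here. Per the labels, the RNA-seq libraries form 6 groups: brain after cardiomyocyte ablation (n = 2), uninjured brain (n = 2), kidney marrow after ablation (n = 2), uninjured kidney marrow (n = 2), and ablated brain of cebpd wild type (n = 3) and cebpd homozygous knockout fish (n = 3).

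The deposited values are counts: whole numbers of reads per gene symbol, with no normalization, for 14781 genes and 5 summary lines per library. Per the submitters' processing notes, which give 1 list of tools for both assays, reads were processed with Trim Galore 0.6.4 and 0.4.1, TopHat2 2.1.1, HTSeq 1.6.1, Bowtie2 2.2.5, SAMtools 1.5, Picard 1.91 and MACS2 on the build danRer10. The gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads outside any gene took 56.6% to 58.3% of the total in the brain libraries and 37.4% to 41.5% in the kidney marrow libraries, and ambiguous reads took 0.254% to 1.23%. The summary lines were left out of all fits.

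The depth was 14364306 to 20469655 gene reads per library in the ablation experiment and 4377028 to 6280007 in the cebpd experiment. The 10 most abundant genes took 8.76% to 22.8% of the gene reads. Spearman correlations of counts across genes between replicates ran from 0.986 to 0.996. The labels do not say that replicates are separate animals, so the p-values measure only the spread between samples.

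Each comparison was fitted in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr, TMM scaling, glmQLFit and glmQLFTest with default settings, and Benjamini-Hochberg adjustment with a threshold of 0.05. Only the groups compared entered a fit, with no replicate block. The 3 main comparisons were ablated against uninjured brain, ablated against uninjured kidney marrow, and cebpd mutant against wild type ablated brain. The difference between the tissues was tested as an interaction over the 8 libraries of the ablation experiment. Levels are CPM on TMM-scaled library sizes, as mean ± SD. Fold changes are on the log2 scale, and their standard errors (SE) were derived from the F statistic. The ratio of a gene with at most 3 reads per library in 1 group has a 95% Clopper-Pearson counting interval, which covers counting error only.

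Before the data were examined, 27 gene lists were fixed, with 983 entries, of which 779 are in the files. They cover the C/EBP family, glucocorticoid-responsive genes, inflammatory cytokine signalling, interferon response, complement and acute-phase plasma proteins, hypoxia and glycolysis, cell cycle, heat shock and unfolded protein response, circadian clock, immediate early genes, ion and water transport and hypothalamic neuropeptides. Markers of cell types and tissues cover anterior pituitary, ependymal cells, radial glia, neurons, oligodendrocytes, microglia and macrophages, endothelial and mural cells, meningeal fibroblasts and extracellular matrix, erythroid cells, photoreceptors and pineal, striated muscle, nephron, neutrophils, lymphocytes, and thrombocytes with haematopoietic progenitors. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a set move, on balance, in 1 direction, and does not compare the set with other genes.

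The genes named follow a rule fixed at the same point. It takes cebpd, up to 10 genes per direction with the largest fold change among those past the threshold, and up to 4 past it in each list. The genes of the first kind need at least 2 CPM in the higher group, libraries of the groups that do not overlap, and a symbol that is not a clone name. Where fewer than 5 genes passed in a direction, the 5 with the smallest p are given. For the tissue difference and the gene sets, up to 5 and up to 4 genes with the smallest p are given. Genes named outside the rule are marked as chosen after their values were seen.

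Genes called in the ablated brain were carried as sets into the kidney marrow and mutant fits, which share no library with the brain comparison. The alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a mean count of at least 50, leaving out each library, a block for the replicate number, wider fits, and an estimated inter-gene correlation. Chosen after seeing the data were the list tests without wild type replicate 1, the brain gene set without each library of the cebpd experiment and without cebpd, the C/EBP list without cebpd, and the overlap of DESeq2 calls between tissues. Gene positions came from the annotation of GRCz12tu, matched by symbol for 14492 of the 14781 genes (98.0%); no annotation of danRer10 was used.

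The pipeline was tested on simulated data with the dispersion and depth of each comparison, with 66 or 67 changed genes per fold. Genes were drawn independently, so shifts shared by many genes of a library were left out. For 1.5-fold, 2-fold and 4-fold changes, it recovered 71.6%, 89.6% and 98.5% in the brain design, and 4.48%, 44.8% and 87.9% in the kidney marrow design. It recovered 62.7%, 91.0% and 95.5% in the mutant design, and 1.49%, 35.8% and 80.3% in the tissue difference design. False calls made up 4.42%, 20.9%, 8.29% and 6.02% of the calls in the same order of designs. A set of 20 raised genes passed camera in all 3 main designs, and a set of 20 unchanged genes passed in none.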

Results

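RNA was sequenced from the brain and whole kidney marrow of adult male zebrafish of the EK strain, 4 to 12 months old. Tissue was taken 7 days after a tamoxifen bath of 17 h at 0.5 to 0.7 µM, the step that ablates cardiomyocytes in the injured groups. Whether uninjured fish went through the bath is not stated. The ablation experiment holds 2 ablated and 2 uninjured libraries for each tissue, with 14364306 to 20469655 gene reads each. The cebpd experiment holds 3 wild type and 3 homozygous mutant libraries of ablated brain, with 4377028 to 6280007. All values rest on deposited read counts, scaled by library size (CPM) and tested with edgeR.

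The brain comparison asks which genes of the brain respond to an injury of the heart. cebpd, which encodes a transcription factor of the C/EBP family, stood at 63.4 and 47.3 CPM in the ablation libraries and at 28.5 and 24.6 CPM in the uninjured ones. Its log2 fold change was 1.05 (SE 0.13, n = 2 per group, edgeR adjusted p = 0.00596). arrdc3b, an arrestin-domain gene, rose by 1.61 (SE 0.13) from 49.7 ± 12.4 to 151 ± 14.0 CPM (adjusted p = 0.000305). The claudin gene cldn5b, a component of tight junctions, rose by 1.29 (SE 0.16), and the transporter gene abcc4 rose by 1.01 (SE 0.10). The chemokine gene cxcl12b fell by 1.31 (SE 0.07), from 110 ± 1.1 to 44.4 ± 3.29 CPM (adjusted p = 1.14e-05). Libraries that do not overlap between groups, which the naming rule asks for, were found in 36.1% of all tested brain genes, where chance gives 33.3%.

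Among 12371 tested genes, edgeR called 35 higher and 21 lower, and 847 had an unadjusted p under 0.05. The further higher genes of the naming rule were mst1 (1.35), the linker histone genes histh1l (1.11) and h1fx (0.85), the lipoprotein lipase gene lpl (1.01), the transporter gene slc16a9b (0.91) and socs3b (0.87), an inhibitor of cytokine signalling. The further lower ones were tmprss2 (-1.40), isg15 (-1.36), rgcc (-0.94), slc38a9 (-0.77), elovl7a (-0.56), the alpha globin gene hbaa1 (-0.59) and 3 genes of sterol synthesis, sqlea (-0.75), hmgcs1 (-0.64) and msmo1 (-0.58). Adjusted p for these 15 genes ran from 0.00852 to 0.0495. DESeq2 called 37 higher and 28 lower, did not call histh1l, h1fx, slc16a9b or slc38a9, and gave no adjusted p for mst1, tmprss2 and isg15.

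The brain counts depended on single libraries and on the fit. Without ablation replicate 1 they were 69 higher and 101 lower, and without ablation replicate 2 they were 99 and 98. Without uninjured replicate 1 they were 27 and 48, and without uninjured replicate 2 they were 25 and 12. Leaving out uninjured replicate 1 ended the calls of mst1, slc16a9b, socs3b, slc38a9, hbaa1 and elovl7a, at log2 fold changes of 1.45, 0.73, 0.76, -0.73, -0.41 and -0.52. Leaving out uninjured replicate 2 ended those of mst1, lpl, tmprss2, slc38a9, sqlea, hmgcs1 and elovl7a, at 1.27, 0.93, -1.32, -0.81, -0.74, -0.61 and -0.59. Without ablation replicate 1 the call of elovl7a ended at -0.43. In a fit with the kidney marrow libraries 0 genes rose and 1 fell, at an edgeR adjusted p of 1 for cebpd (2.79e-35 to 1 over its alternatives). Without a low-count filter 36 genes were lower.

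Of the 27 lists, 5 stood higher in the ablated brain by camera. By fry none of the 27 passed in either direction (smallest fry adjusted p = 0.0900). None of the 5 passed with an estimated correlation, at adjusted p = 0.560 for all but neutrophils, where adjusted p = 0.591. All 7 C/EBP genes had a fold change above 0 (median 0.19, adjusted p = 5.47e-06, or adjusted p = 0.560 with an estimated correlation). Over all genes cebpd passed, and cebpd and cebpg (0.19) passed when adjusted over the list alone. The list holds cebpd (1.05) and was not tested without it in brain. Endothelial and mural genes had a median of 0.10 with 19 of 29 above 0 (adjusted p = 0.00206, or adjusted p = 0.560 with an estimated correlation). Of these, cldn5b and the vascular transcription factor gene fli1a (0.56) rose over all genes, and adjusted over the list alone 3 rose and 1 fell. The other higher lists were inflammatory cytokine signalling (median 0.08, 13 of 19 above 0, adjusted p = 0.0225), glucocorticoid-responsive genes (0.10, 15 of 21, adjusted p = 0.0327) and neutrophils (0.13, 15 of 22, adjusted p = 0.0469); with an estimated correlation adjusted p = 0.560, 0.560 and 0.591. Adjusted over the list alone, these 3 lists had 2 higher genes (socs3b, junba), 1 higher and 1 lower (ddit4 at 0.35, sgk1 at -0.31), and 1 higher (ncf1 at 0.74). Leaving out uninjured replicate 1 ended the calls of fli1a (0.50) and socs3b (0.76).

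Another 6 lists stood lower in the ablated brain. Of the 19 interferon-response genes 1 was above 0 (median -0.36, adjusted p = 2.03e-12, or adjusted p = 0.560 with an estimated correlation); isg15, a ubiquitin-like protein induced by interferon, fell over all genes, from 8.42 ± 0.499 to 3.27 ± 0.161 CPM, and 10 fell when adjusted over the list alone, dhx58 (-0.74) and mxe (-0.77) among them. The mean level of the list was 3.04 to 3.07 log2 CPM after ablation and 3.35 to 3.55 without. Photoreceptor and pineal genes had a median of -0.44 with 6 of 30 above 0 (adjusted p = 6.90e-11, or adjusted p = 0.560 with an estimated correlation), and 8 fell adjusted over the list alone, such as grk1a (-2.52). Their mean level overlapped between groups, at 1.32 to 2.44 log2 CPM after ablation and 2.4 to 3.08 without. Myelin genes had a median of -0.11 with 5 of 16 above 0 (adjusted p = 0.00731, or adjusted p = 0.560 with an estimated correlation), and adjusted over the list alone 6 fell, such as ugt8 (-0.31) and plp1b (-0.19), and 1 rose. The other lower lists were cell cycle (-0.12, 9 of 30, adjusted p = 0.0225), neurons (-0.04, 11 of 36, adjusted p = 0.0315) and erythroid cells (-0.06, 8 of 21, adjusted p = 0.0401), each at adjusted p = 0.560 with an estimated correlation. Adjusted over the list alone these 3 had 0, 0 and 1 lower genes, the last being hbaa1, whose call ended without uninjured replicate 1 (-0.41).

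The remaining 16 lists did not pass in the brain, at adjusted p of 0.0534 for extracellular matrix, 0.0554 for striated muscle, 0.0829 for heat shock and ependymal cilia, 0.141 for immediate early genes, 0.266 for ion and water transport, 0.377 for complement, 0.391 for radial glia and nephron, 0.414 for neuropeptides and microglia, 0.429 for the circadian clock, 0.596 for hypoxia, 0.855 for pituitary, 0.932 for lymphocytes and 0.961 for thrombocytes. Single members passed over all genes: the fibronectin gene fn1b (0.63) and the keratin genes krt8 (0.41) and krt18 (0.45) rose, as did the gap junction gene cx43 (0.26), while the aromatase gene cyp19a1b (-0.35), the glucose transporter gene slc2a1a (-0.49), klf2a (-0.54) and podxl (-0.36) fell. The median and the camera direction had opposite signs for hypoxia, pituitary, microglia, extracellular matrix and nephron, and the mean differed in sign from the median for all of these but microglia, and also for lymphocytes. Without uninjured replicate 1 the calls of krt18, cx43, cyp19a1b, slc2a1a, klf2a and podxl ended at 0.38, 0.28, -0.31, -0.42, -0.55 and -0.33. Without uninjured replicate 2 those of cx43, cyp19a1b, klf2a and podxl ended at 0.24, -0.39, -0.53 and -0.39, and without ablation replicate 1 that of klf2a at -0.45. DESeq2 did not call klf2a.

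**Figure D1:**
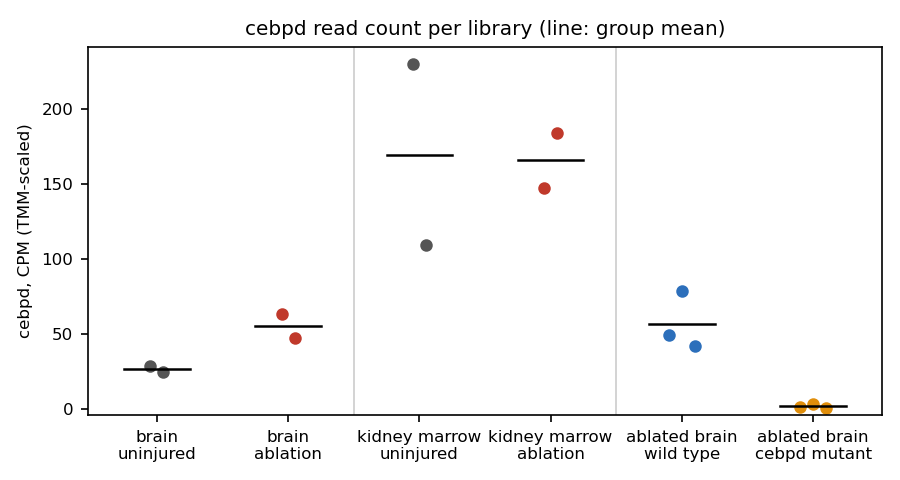
Each point is 1 library, with cebpd in CPM on the vertical axis and the group on the horizontal axis; lines are group means. The uninjured brain libraries lie at 28.5 and 24.6 CPM and the ablated ones at 63.4 and 47.3 CPM, and the mutant libraries lie at 3.05 CPM or lower.

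The kidney marrow comparison asks for the same response in the main blood-forming organ of the fish. Cell cycle genes stood higher after ablation: all 32 tested members were above 0, with a median log2 fold change of 0.98 (n = 2 per group, camera adjusted p = 3.69e-24, or adjusted p = 0.510 with an estimated correlation), such as rrm2 (1.17, SE 0.15), a subunit of ribonucleotide reductase, and pcna (0.99, SE 0.17), the DNA polymerase clamp. Erythroid genes had 23 of 24 members above 0 and a median of 0.50 (adjusted p = 1.44e-08, or adjusted p = 0.510 with an estimated correlation), such as urod (1.17, SE 0.19), an enzyme of haem synthesis. Interferon-response genes stood lower, with 0 of 19 above 0 and a median of -0.61 (adjusted p = 2.75e-14, or adjusted p = 0.364 with an estimated correlation), such as mxc (-2.17, SE 0.19) and isg15 (-1.57, SE 0.21). cebpd did not change by the test, at 147 and 184 CPM after ablation and 230 and 109 CPM without (log2 fold change -0.03, SE 0.36, edgeR adjusted p = 0.966). Its sign turned without ablation replicate 1 (0.12) and without uninjured replicate 1 (0.60).

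No single kidney marrow gene passed. edgeR called 0 genes higher and 0 lower of 12160 tested, with 2384 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0740; DESeq2 called 434 and 170. The smallest p in the higher direction belonged to si:dkey-226m8.7 (1.96), fhl2a (1.73), fabp10a (2.49), the ceruloplasmin gene cp (1.89) and htra3a (1.93), and in the lower direction to mxc (-2.17), slc26a6l (-1.07), the polyamine acetyltransferase gene sat1a.1 (-1.12), ahr1a (-1.23) and the metallothionein gene mt2 (-1.01), all at adjusted p = 0.0740. The biological coefficient of variation was 16.5%, against 5.56% in the brain comparison. Groups did not overlap in 6334 genes, 52.1% of those tested, where chance gives 33.3%. A fit with the brain libraries gave 912 and 440, and leaving out ablation replicate 2 gave 1 higher gene.

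Besides cell cycle and erythroid genes, 6 lists stood higher in the ablated kidney marrow by camera, and none of them passed with an estimated correlation. By fry none of the 26 lists tested passed in either direction (smallest fry adjusted p = 0.106). Endothelial genes had 20 of 29 members above 0 (median 0.23, adjusted p = 5.23e-05, or adjusted p = 0.364 with an estimated correlation), such as stab2, a scavenger receptor of sinusoidal endothelium, at 530 ± 208 against 63.1 ± 3.34 CPM (3.07, SE 0.30), and cldn5b (1.84). Thrombocyte and progenitor genes had 17 of 21 above 0 (median 0.42, adjusted p = 5.23e-05, or adjusted p = 0.364 with an estimated correlation), such as the integrin genes itgb3b (1.33) and itga2b (0.96). Inflammatory genes had 19 of 25 (median 0.38), complement and acute-phase genes 12 of 18 (0.86) and heat shock genes 22 of 31 (0.35), each at adjusted p = 0.00198, and with an estimated correlation at adjusted p = 0.364, 0.550 and 0.510. The mean level of the complement list overlapped between groups, at 2.93 and 4.41 log2 CPM after ablation and 2.98 and 3.16 without. Among these lists socs3b (1.56), c6 (1.35), fgb (2.37) and calr (0.74) are examples. Extracellular matrix genes had 15 of 23 above 0 (median 0.25, adjusted p = 0.00437, or adjusted p = 0.576 with an estimated correlation), such as fn1a (0.95). Over all genes edgeR called 0 members in any list, while DESeq2 called some, cldn5b and socs3b among them. Adjusted over the list alone, 26 cell cycle, 9 erythroid, 6 endothelial, 7 thrombocyte, 6 inflammatory, 3 complement, 4 heat shock and 5 matrix genes rose, and 1 thrombocyte and 1 inflammatory gene fell.

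Besides interferon-response genes, 6 lists stood lower in the ablated kidney marrow, and none of them passed with an estimated correlation. Nephron genes had 12 of 46 members above 0 (median -0.34, adjusted p = 1.37e-05, or adjusted p = 0.510 with an estimated correlation), such as the peptide transporter gene slc15a2 (-0.69) and hnf4a (-0.68). Lymphocyte genes had 3 of 28 above 0 (-0.44, adjusted p = 0.000105, or adjusted p = 0.364 with an estimated correlation), such as lck (-0.81) and the recombination gene rag1 (-0.61). Circadian clock genes had 7 of 38 (-0.29), striated muscle genes 2 of 27 (-0.78) and neuronal genes 6 of 36 (-0.32), each at adjusted p = 0.00198, and with an estimated correlation at adjusted p = 0.364, 0.576 and 0.510. The mean level of the muscle list overlapped between groups, at 2.21 and 3.112 log2 CPM after ablation and 3.108 and 3.55 without. Neutrophil genes had 8 of 27 above 0 (-0.16, adjusted p = 0.0207, or adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, and nephron genes aside, 14 interferon genes fell, 1 circadian and 1 muscle gene rose, and 0 lymphocyte, neuronal or neutrophil genes passed. The other 11 of the 26 lists tested were at adjusted p of 0.0694 to 0.691, and for immediate early genes and neuropeptides the median lay below 0 where mean and camera lay above.

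**Figure D2:**
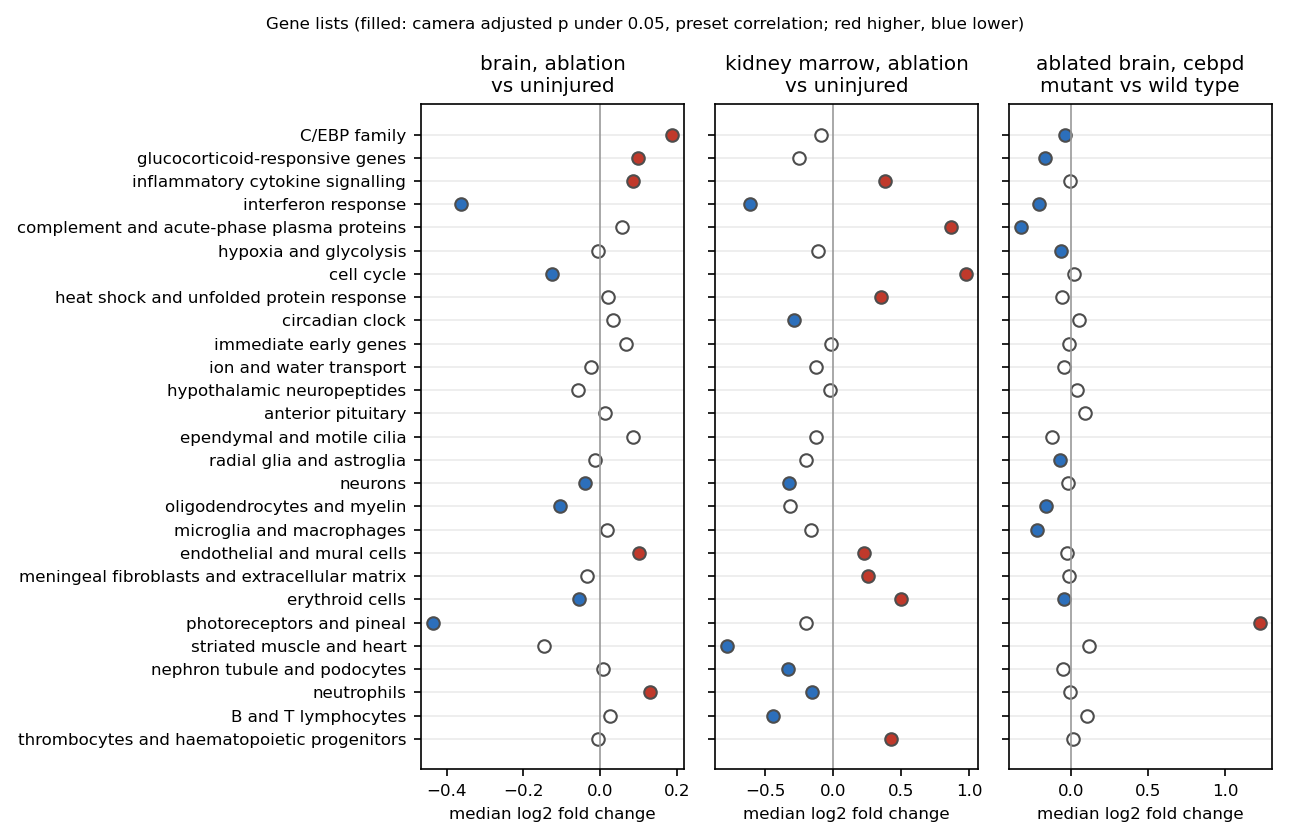
Each point is the median log2 fold change (horizontal axis) of a gene list (vertical axis) in the comparison named above its panel; the horizontal scales differ. Filled points passed camera at the preset correlation, red for higher and blue for lower, and none passed with an estimated correlation. Interferon-response genes lie at -0.36, -0.61 and -0.21.

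The cebpd comparison asks which genes of the ablated brain differ with the genotype of cebpd. cebpd itself stood at 49.4, 78.4 and 41.7 CPM in the wild type libraries and at 1.3, 3.05 and 0.906 CPM in the mutant ones, a log2 fold change of -4.96 (SE 0.33, n = 3 per group, edgeR adjusted p = 1.32e-05). Genes that fell in the mutants included the acid-sensing ion channel gene asic1c, by 1.83 (SE 0.20) from 16.3 ± 2.94 to 4.52 ± 0.227 CPM, the chemokine gene ccl25b, by 1.22 (SE 0.13) from 34.1 ± 3.49 to 14.6 ± 0.713 CPM, and the cohesin gene smc1a, by 1.16 (SE 0.14). saga, the arrestin of photoreceptors, rose by 2.14 (SE 0.27) from 3.54 ± 1.80 to 16.5 ± 2.04 CPM (adjusted p = 0.00321). The crystallin gene crybb1l3 had 1 to 3 reads in each wild type library and 22 to 30 in each mutant one, a ratio of 11.6 (counting interval 5.07 to 32.5; adjusted p = 0.00321).

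Of 11103 genes tested, edgeR called 4 higher and 11 lower in the mutants, with 944 at an unadjusted p under 0.05; DESeq2 called 11 and 33. The other higher genes were rbbp8 (1.24, SE 0.17) and gstk1 (0.57, SE 0.10). The other lower ones were fat3a (-1.92), the muscarinic receptor gene chrm2a (-1.43), plxnb2b (-0.86), the intermediate filament gene vim (-0.65), sncga (-0.48) and 2 genes with clone names. The crystallin gene cryba1a (2.11) did not pass, at adjusted p = 0.0535. asic1c, rbbp8 and vim lie on the chromosome of cebpd in the GRCz12tu annotation. Groups did not overlap in 1523 genes, 13.7% of those tested, where chance gives 10%.

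The mutant counts moved with most libraries. They were 2 higher and 5 lower without wild type replicate 1, 12 and 77 without wild type replicate 3, 7 and 10 without mutant replicate 1, 2 and 5 without mutant replicate 2, and 2 and 4 without mutant replicate 3. Without wild type replicate 2 they were 6 and 9. The calls of cebpd, crybb1l3, saga, asic1c, ccl25b and smc1a held without any 1 library. That of gstk1 ended without each library in turn (0.48 to 0.61). Without wild type replicate 1 the calls of rbbp8 (1.15), chrm2a (-1.19), plxnb2b (-0.77), vim (-0.61) and sncga (-0.50) ended, without wild type replicate 2 those of chrm2a (-1.42) and plxnb2b (-0.74), and without mutant replicate 1 those of chrm2a (-1.47) and plxnb2b (-0.80). Without mutant replicate 2 those of rbbp8 (1.21), fat3a (-1.84), chrm2a (-1.46), plxnb2b (-0.89) and sncga (-0.46) ended, and without mutant replicate 3 those of rbbp8 (1.28), fat3a (-1.89), chrm2a (-1.37), plxnb2b (-0.90), vim (-0.58) and sncga (-0.47). cryba1a passed without wild type replicate 3 (2.84), without mutant replicate 1 (2.31), by DESeq2 (2.15), with no low-count filter (2.12) and in a fit of all 10 brain libraries (2.11). No low-count filter gave 14 and 27 genes, a stricter filter 2 and 10, and a fit of all 10 brain libraries 10 and 18.

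Photoreceptor and pineal genes stood higher in the mutants, with 25 of 26 members above 0, a median of 1.23 and camera adjusted p = 5.83e-31, or adjusted p = 0.169 with an estimated correlation. saga passed over all genes, and 20 members passed adjusted over the list alone, such as aanat2 (1.5, SE 0.34), the melatonin synthesis enzyme of the pineal. Their mean level was 1.08, 3.11 and 3.25 log2 CPM in the wild type libraries and 3.89, 4.21 and 3.54 in the mutants. Wild type replicate 1 thus stood apart from the other wild type libraries, and without it the median was 0.78, with 26 of 26 above 0, 16 past adjusted over the list alone and adjusted p = 0.211 with an estimated correlation.

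**Figure D3:**
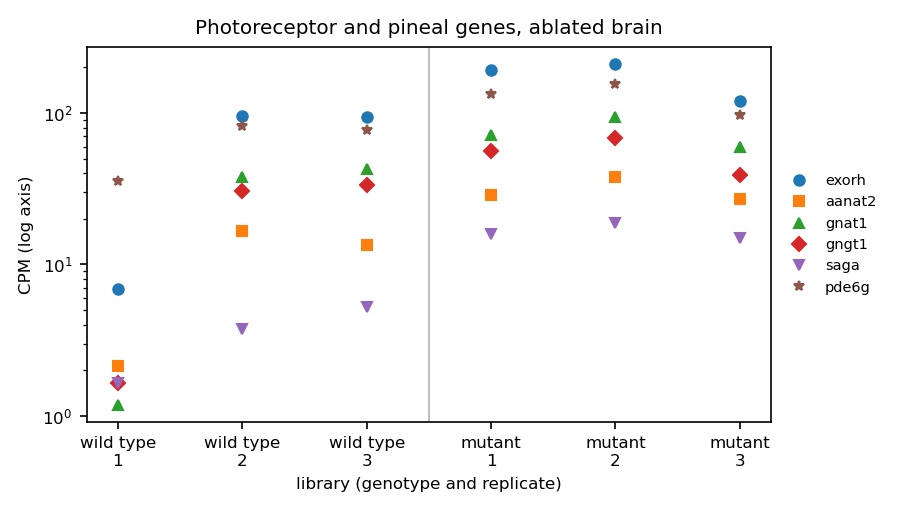
Levels of 6 photoreceptor and pineal genes in CPM (logarithmic vertical axis) in each library of the cebpd experiment (horizontal axis); each symbol is 1 gene, and exorh, gnat1 and gngt1 were chosen after their values were seen. aanat2 lies at 2.14 CPM in wild type replicate 1, at 16.6 and 13.4 CPM in the other wild type libraries, and at 27.0 to 37.8 CPM in the mutants.

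Of the 27 lists, 9 stood lower in the mutants by camera, and none of them passed with an estimated correlation. Myelin genes had 1 of 15 members above 0 (median -0.16, adjusted p = 1.86e-05, or adjusted p = 0.135 with an estimated correlation), such as plp1a (-0.36) and mpz (-0.28). Microglia and macrophage genes had 4 of 22 above 0 (-0.23, adjusted p = 4.85e-05), glucocorticoid-responsive genes 5 of 21 (-0.17, adjusted p = 0.000165), such as ddit4 (-0.50) and the glutamine synthetase gene glula (-0.36), and interferon-response genes 2 of 13 (-0.21, adjusted p = 0.00119), such as isg15 (-0.88) and stat2 (-0.33). For these 3 lists adjusted p = 0.261, 0.178 and 0.163 with an estimated correlation. Erythroid genes had 7 of 21 above 0 (-0.05, adjusted p = 0.00136), hypoxia and glycolysis genes 7 of 30 (-0.06, adjusted p = 0.0147), radial glia genes 9 of 26 (-0.07, adjusted p = 0.0251) and complement genes 2 of 10 (-0.33, adjusted p = 0.0366). For these 4 lists adjusted p = 0.178, 0.433, 0.323 and 0.237 with an estimated correlation. The mean level overlapped between genotypes for glucocorticoid-responsive genes (5.73 to 5.882 log2 CPM in mutants, 5.867 to 6.10 in wild type) and for hypoxia genes (6.19 to 6.39 and 6.32 to 6.42). The C/EBP family passed (median -0.04, 3 of 7 above 0, adjusted p = 3.48e-06, or adjusted p = 0.135 with an estimated correlation) through cebpd, and without cebpd it had adjusted p = 0.645 with 3 of 6 above 0. Over all genes cebpd and vim fell, and adjusted over the list alone 2 myelin, 2 glucocorticoid-responsive, 2 interferon, 3 erythroid, 1 radial glia and 1 C/EBP gene fell. Without wild type replicate 1 the hypoxia list (adjusted p = 0.0706), the radial glia list (adjusted p = 0.114) and the call of vim (-0.61) did not pass, and without mutant replicate 3 that of vim (-0.58) did not.

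Fry, which asks whether a list's genes move on balance in 1 direction, gave adjusted p = 0.0402 for the C/EBP family and 0.0342 for interferon-response genes. The C/EBP family holds the mutated gene cebpd, and fry was not run on it without cebpd. The other 17 lists did not pass camera. Of these, the circadian clock list (adjusted p = 0.275) had 3 higher and 4 lower genes adjusted over the list alone, among them the repressor genes nr1d1 (0.79), nr1d4a (0.53) and nr1d4b (0.72), and clocka (-0.41). Mean and median differed in sign for neuropeptides and thrombocytes, and for extracellular matrix both lay below 0 where camera pointed above.

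The tissue comparison tests whether the ablation response differs between brain and kidney marrow. edgeR called 5 genes with a higher and 29 with a lower response in brain of 13077 tested, with 2091 at an unadjusted p under 0.05; DESeq2 called 99 and 165. sat1a.1 (1.43, SE 0.15), slc43a2b (1.41, SE 0.16), mtmr7a (1.44, SE 0.18), mt2 (1.11, SE 0.16) and gstr (0.72, SE 0.10) had the higher difference, and cp (-1.94, SE 0.16), tmem35 (-1.46, SE 0.14), rgs7bpa (-1.71, SE 0.17), sae1 (-1.46, SE 0.15) and the neurotrophin gene bdnf (-2.35, SE 0.24) the lower one, at adjusted p of 0.0245 to 0.0462. None of these genes was called in the brain or the kidney marrow comparison alone. For cp the kidney marrow level was 66.8 CPM after ablation and 18.0 CPM without, and the brain level 559 and 580 CPM. bdnf was near the floor in kidney marrow, at 1.985 and 0.431 CPM, and its brain fold change was -0.16 (edgeR adjusted p = 0.717). Low kidney marrow levels were also found for tmem35 (4.97 and 1.94 CPM), rgs7bpa (7.44 and 2.18 CPM) and mtmr7a (2.57 and 7.27 CPM). The difference for cebpd was 1.09 (SE 0.45, adjusted p = 0.293), so its response was not shown to differ between tissues. Leaving out any of the 4 brain libraries gave 0 and 0 genes and ended the calls of all 10 genes named, at adjusted p of 0.190 to 0.290; the differences without them were 1.34 to 1.51 for sat1a.1, 0.98 to 1.23 for mt2, -2.02 to -1.86 for cp and -2.43 to -2.26 for bdnf. Without uninjured kidney marrow replicate 1 the counts were 115 and 198, without replicate 2 they were 18 and 39, and without ablated replicate 1 or 2 they were 15 and 28 or 14 and 24. Leaving out ablated kidney marrow replicate 1 or 2 also ended the call of mt2 (1.19 or 1.13), and replicate 2 that of gstr (0.74).

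Genes called in the ablated brain were then followed in kidney marrow. Of the 35 higher genes 24 were above 0 there (median 0.27, camera adjusted p = 4.61e-06, or adjusted p = 0.187 with an estimated correlation), and of the 21 lower genes 15 were below 0 (median -0.19, camera adjusted p = 0.00887, or adjusted p = 0.187 with an estimated correlation). The smallest p belonged to wu:fj16a03 (1.67), socs3b (1.56), cldn5b (1.84) and slc16a9a (1.24) in the first set, and to isg15 (-1.57), slc38a9 (-1.21), acat2 (0.77) and msmo1 (-0.65) in the second. With the 100 genes of smallest p in brain per direction instead, 54 of 97 were above 0 in the first set (median 0.07) and 68 of 87 below 0 in the second (median -0.34). By DESeq2, 9 genes were higher in both tissues where chance gives 1.15 (of 35 and 264 among 8049, Fisher's exact test, p = 1.28e-06). The separate DESeq2 comparisons called 37 and 434 higher genes, and edgeR called 0 in kidney marrow. In the other direction 1 gene, msmo1, was lower in both where chance gives 0.283 (Fisher's exact test, p = 0.248). This overlap was chosen after seeing the data. Fisher's test takes genes as independent, which they are not, so these p-values are smaller than the evidence warrants. Across 11444 genes the correlation of fold changes between tissues was 0.09 (Pearson) and 0.07 (Spearman); genes are not independent replicates.

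The same sets were followed in the mutants. Of the 35 genes higher in the ablated brain 33 were tested and 30 were below 0 in mutant against wild type (median -0.28, camera adjusted p = 7.44e-15, or adjusted p = 0.198 with an estimated correlation; fry adjusted p = 0.304). The smallest p belonged to cebpd (-4.96), si:dkey-85k7.7 (-0.66), arrdc3b (-0.79) and wu:fj16a03 (-0.25), and with the 100 genes of smallest p in brain 77 of 97 were below 0 (median -0.15). Over all genes 1 of them, cebpd, fell, and 13 lay lower and 1 higher at an unadjusted p under 0.05. Without cebpd the median was -0.26 with 29 of 32 below 0 (camera adjusted p = 2.57e-09, or adjusted p = 0.337 with an estimated correlation; fry adjusted p = 0.467). The mean level of the set without cebpd overlapped between genotypes, at 6.37, 6.92 and 6.47 log2 CPM in wild type and 6.49, 6.38 and 6.19 in mutants (exact permutation p = 0.5, where 0.1 is the smallest that 3 against 3 allows). Leaving out wild type replicate 2, the highest of these, gave a median without cebpd of -0.07 with 23 of 32 below 0. The genes lower in the ablated brain did not pass in the mutants (12 of 20 below 0, median -0.09, camera adjusted p = 0.0803). Of these, hbaa1 (-0.41), isg15 (-0.88), klf2a (0.29) and lgals2a (-0.26) had the smallest p. The lower set passed, also toward lower, with the 100 genes of smallest p in brain (53 of 84 below 0, camera adjusted p = 0.00265). The same held without wild type replicate 2 (adjusted p = 0.00292) and without mutant replicate 3 (adjusted p = 0.00938). The direction of the set turned without wild type replicate 1 (adjusted p = 0.710), and adjusted p ranged from 0.00265 to 0.735.

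**Figure D4:**
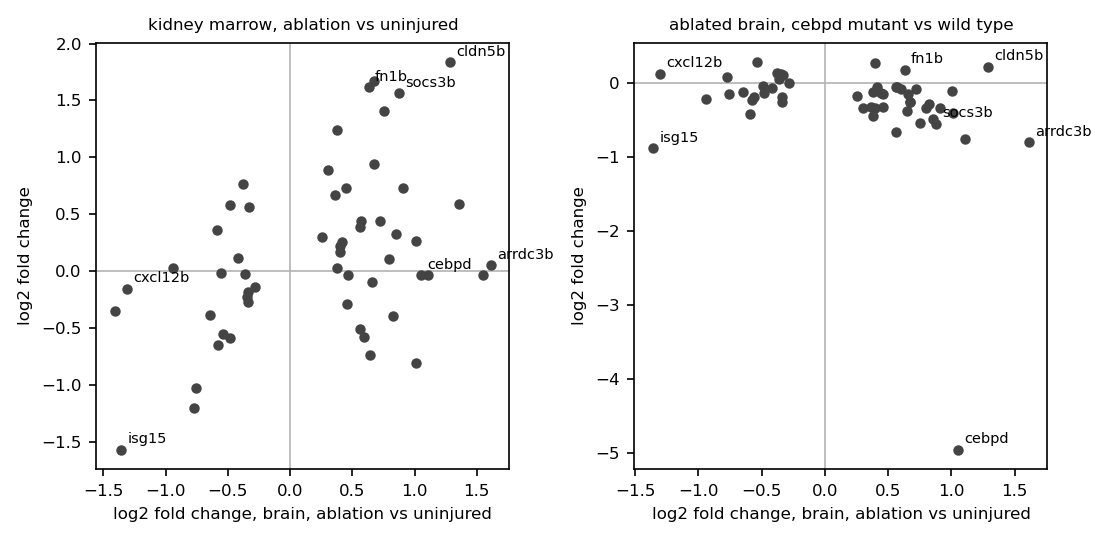
Each point is a gene called in the ablated brain, with its log2 fold change there on the horizontal axis and in kidney marrow (left) or in mutant against wild type ablated brain (right) on the vertical axis. cldn5b lies at 1.29 in brain and 1.84 in kidney marrow, and cebpd at 1.05 in brain and -4.96 in the mutants.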

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

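The linkage tests, the spread of the pineal genes and the test without wild type replicate 2 were chosen only after the results were seen.

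A test of the difference between the tissues marked 5 genes whose ablation response was higher in brain than in kidney marrow and 29 whose response was lower. The genes with the smallest p differed, as brain minus kidney marrow on the log2 scale, by 1.43 (sat1a.1), 1.41 (slc43a2b), 1.44 (mtmr7a), 1.11 (mt2) and 0.72 (gstr), and by -1.94 (cp), -1.46 (tmem35), -1.71 (rgs7bpa), -1.46 (sae1) and -2.35 (bdnf). None of these genes was called in the brain comparison, and edgeR called 0 genes in the kidney marrow comparison. For cp the fold change was -0.05 in brain and 1.89 in kidney marrow, and for mt2 it was 0.10 and -1.01. For bdnf it was -0.16 and 2.19, at 1.985 and 0.431 CPM in ablated and uninjured kidney marrow. Leaving out any 1 of the 4 brain libraries (ablation replicate 1 or 2, uninjured replicate 1 or 2) left 0 and 0 genes by edgeR.

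Photoreceptor and pineal genes stood higher in the cebpd mutant libraries, by 1.40 log2 CPM on average. The dissections may have held unequal amounts of pineal or retinal tissue, but the test leaves this open: the mean of these genes had an SD of 1.21 among the wild type libraries, below that difference. The SD rests on wild type replicate 1, and without it the SD was 0.0971 and the difference 0.70. In the ablation experiment the list also varied within groups, with an SD of 0.79 between ablated and 0.48 between uninjured brain libraries. An effect of cebpd on pineal genes is not ruled out, since all 3 mutant libraries lay above all 3 wild type libraries. Chance gives groups that do not overlap in 10% of genes. The share of pineal tissue in each dissection was not measured.

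Of the 14 genes called in the mutants that have a position, 4 lie on the chromosome of cebpd: cebpd, asic1c, rbbp8 and vim. A haplotype that travels with the mutant allele may account for part of this: a p under 0.01 was more frequent on that chromosome than elsewhere (17 of 305 genes against 252 of 10679, odds ratio 2.44, Fisher's exact test, p = 0.00183), and on it more frequent among the genes nearer to cebpd (15 of 152 against 2 of 153, odds ratio 8.22, p = 0.000952). These counts leave out cebpd but hold asic1c, rbbp8 and vim, which prompted the tests; without the called genes the odds ratios were 2.09 (Fisher's exact test, p = 0.0174) and 6.58 (p = 0.00563). Neighbouring genes are not independent, so these p-values are smaller than the evidence warrants. Which of these genes respond to the loss of cebpd itself stays open, as no sequence variants were examined.

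Genes higher in the ablated brain lay lower in the cebpd mutants. A shift shared by genes of like expression is argued against by 0 of 10000 expression-matched random sets with a median as low. The median without wild type replicate 1 was -0.34, which decides nothing about that library, since its level of the set was the lowest in wild type (6.37 log2 CPM). Wild type replicate 2 may account for much of the pattern, since the median without it was -0.0715. A lower response to injury in the mutants stays a hypothesis. Such a response would put the genes lower in the ablated brain above 0 in the mutants, but 12 of 20 lay below 0 (median -0.09). Across 11073 genes the correlation of fold changes between the brain and mutant comparisons was -0.008 (Pearson) and 0.04 (Spearman). Most of these genes were not called in brain, so this value says little about a lower response. Among 52 genes called in brain, cebpd aside, it was -0.29 and -0.32, with 37 of opposite and 15 of the same sign. These are the genes in which the pattern was seen, and genes are not independent replicates. As uninjured brains of both genotypes were not analysed here, whether the difference between genotypes precedes the injury stays open.

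The 10 splits of the 6 libraries of the cebpd experiment are too few for a share under 0.05. The real split called 15 genes and the highest other 0, so only the real split reached its value. For the median of the brain genes without cebpd, regardless of sign, the real value was 0.26 and the highest other 0.31. Here 3 of the 10 splits, the real one among them, reached the real value. For lists past the threshold the real value was 10 and the highest other 8, so again only the real split reached its value.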

How the results depend on the processing

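The tests of the brain gene sets without each library of the cebpd experiment, the list tests without wild type replicate 1, and the tests without cebpd were chosen after seeing the data. Calls rest on 2 or 3 libraries per group, and where 1 of 2 was left out, the lone library is assumed to vary like the other groups. The cause of each shift below was not tested. Of 666 alternative values for the 61 results on named genes, 6 had no adjusted p: mst1, tmprss2 and isg15 by DESeq2, and mst1, crybb1l3 and cryba1a under the stricter filter. Of those for brain 218 stayed on the same side of the threshold and 58 lost the call, for kidney marrow 70 stayed and 30 gained one, for the mutants 121 stayed, 27 lost and 6 gained one, and for the tissue difference 87 stayed and 43 lost it. In simulated data of the kidney marrow depth and fitted dispersions 44.8% of 2-fold changes were recovered, against 89.6% in the brain design. False calls made up 20.9% and 4.42% of the calls. Genes were drawn independently there, so shifts shared by many genes of a library, and their effect on recovery, are not covered.

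Leaving out 1 library at a time gave 25 to 99 higher and 12 to 101 lower genes in brain, 0 to 1 higher in kidney marrow (with all libraries edgeR called 0, with 2384 genes of both directions at an unadjusted p under 0.05, and DESeq2 called 434 higher and 170 lower), 2 to 12 higher and 4 to 77 lower in the mutants, and 0 to 115 higher and 0 to 198 lower in the tissue difference. It gave 0.83 to 1.26 for cebpd in brain, -0.47 to 0.60 in kidney marrow, where it turned the sign without ablation replicate 1 (0.12) and uninjured replicate 1 (0.60), -5.64 to -4.65 in the mutants and 0.50 to 1.58 for the tissue difference. For the genes called in brain, camera at the preset correlation gave adjusted p of 6.37e-24 to 5.48e-06 in the mutants for the higher set. That set holds cebpd, the mutated gene, and its estimated correlation with all libraries was 0.53. Without cebpd its median ran from -0.34 to -0.07, the last without wild type replicate 2. The lower set had adjusted p of 0.00292 to 0.735, with the direction turned without wild type replicate 1 (0.710).

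DESeq2 gave 434 higher and 170 lower genes in kidney marrow, 11 and 33 in the mutants, and 99 and 165 in the tissue difference. With no low-count filter 36 genes were lower in brain, and 14 were higher and 27 lower in the mutants; with the stricter filter 2 were higher there. With both tissues in 1 fit, 0 genes rose and 1 fell in brain by edgeR, with 847 at an unadjusted p under 0.05 in the fit of brain alone and 37 and 28 by DESeq2; cebpd had 1.06 without passing. That fit gave 912 and 440 genes in kidney marrow. With all 10 brain libraries in 1 fit the mutants had 10 and 18. The 100 genes with the smallest p as the lower set gave camera adjusted p = 0.00265 in the mutants, also toward lower. With an estimated inter-gene correlation 0 lists passed in any of the 3 comparisons, and the brain sets had adjusted p = 0.198 (higher set, mutants), 0.187 (higher set, kidney marrow) and 0.187 (lower set, kidney marrow).

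The replicate numbers pair nothing in the labels. Deviations of same-numbered libraries had correlations of -0.01 in brain, 0.06 in kidney marrow and -0.06, -0.01 and -0.05 in the mutants. In the brain and mutant comparisons no library correlated best with its own number, and in kidney marrow each did. With 2 libraries per group this is set by the sign of the correlation alone. A replicate block gave 163 higher and 195 lower genes in brain, 433 and 165 in kidney marrow, 22 and 44 in the mutants, and 20 and 88 in the tissue difference. With the block cebpd in kidney marrow had 0.0533, and neutrophil genes in brain had adjusted p = 0.0510, cryba1a passed in the mutants (2.16), and the 10 genes with the smallest p in kidney marrow passed at adjusted p = 0.0420. RLE scaling kept every count of genes within 1.5 times its value.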

Other observations

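The sterol synthesis list was chosen only after 4 of its genes were seen among the calls, and the lens list after crybb1l3; the test of the sterol genes that were not called was written before it was run.

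Genes of sterol synthesis stood lower in the ablated brain. All 24 tested members of a list of 28 had a fold change below 0 (median -0.36), and 4 fell over all genes: msmo1 (-0.58), sqlea (-0.75), hmgcs1 (-0.64) and acat2 (-0.37). Adjusted over the list alone, 15 passed. The mean level of the list was 4.15 and 4.36 log2 CPM in the ablation libraries and 4.62 and 4.63 in the uninjured ones (camera p = 3.73e-29, or 0.0396 with an estimated correlation; fry p = 0.0524). Leaving out uninjured replicate 2 ended the calls of sqlea (-0.74) and hmgcs1 (-0.61), and the median of the list was -0.31 to -0.49 without any 1 library. Whether the call of acat2 held with a library left out was not checked. In kidney marrow 15 of 24 members were below 0 and in the mutants 15 of 23, and neither passed camera.

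A hypothesis is that expression falls across the sterol synthesis pathway of the brain after cardiac injury. The 20 members that were not called had a median of -0.32, and 20 of 20 were below 0, where random sets of the same size had a 2.5% point of -0.06. Random sets do not carry the shared movement of genes in a pathway, so their 2.5% point may be too narrow for this list. With an estimated correlation the whole list, called genes included, had camera p = 0.0396, and fry gave p = 0.0524. The hypothesis was formed and tested on the same 4 libraries. Any shift shared by these genes between those libraries would give the same result, so this test cannot decide the hypothesis.

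Of 43 lens genes listed, 39 are in the files and 5 were tested in the mutant comparison. crybb1l3 and cryba1a had fold changes of 3.45 and 2.11, and cryabb, crygn2 and lim2.2 had -0.29, -0.22 and -0.36.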
